A study of Mus musculus with 12 samples.

How the data were processed

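Bulk RNA-seq of mouse intestine was analysed from 12 libraries in 4 groups of 3. The groups combine genotype (floxed or IEKO) with diet (chow or HFD), taken from the sample titles and genotype and treatment labels. Total RNA was isolated with a column kit and libraries were made with a stranded total RNA kit, per the labels' protocols. The labels give the tissue as intestine and name no segment, no recombinase line and no deleted exons.

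The deposited table holds expected counts per gene, estimates of reads that need not be whole, and they were not scaled between libraries. In each library 12.3% to 13.2% of genes had a value that was not whole. Trimmomatic, STAR, Picard, RSEM and the mouse build mm10 were used, per the submitters' processing notes, which give no versions or roles. The annotation release and the strand setting used in counting are not given in the sources used here. RSEM shares reads among genes with similar sequence, so values of near-identical family members are uncertain, and counts of a gene and of its antisense partner may hold each other's reads.

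The table held 47643 genes, and 18495 of these had no count in any library. Gene IDs were matched to symbols and mm10 coordinates through GENCODE vM21, which may not be the release the authors used, and 47224 IDs matched. For 60 IDs the symbol was already held by another ID. Total expected counts per library ran from 33620991 to 53959367, so that 1 CPM, a count scaled by library size, stood for 33.6 to 54.0 counts before scaling. CPM values in the text were computed from the rounded counts and TMM-scaled library sizes.

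Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood F test, robust fit, TMM factors, filterByExpr with default settings) in R 4.3.3. All 12 libraries entered a single fit of 4 group means. Contrasts were IEKO against floxed on each diet, HFD against chow in each genotype, the genotype by diet interaction, and the genotype difference averaged over diets. Of all genes, 17602 passed the filter and were tested, and p-values were adjusted by Benjamini and Hochberg within each contrast with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Gene lists were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01. Of 47 lists, a list of sex-linked genes served as a label check and was left out of the test. The 45 others with at least 4 measured members were tested, and p-values were adjusted over these 45.

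The contrasts, the gene lists, the other settings to be tried and the rule for named genes were set before the data were examined. The rule named Ppara in every contrast. For each pairwise contrast it named the 8 largest increases and 8 largest decreases among genes with adjusted p under 0.05, mean log2 CPM of at least 1, groups not overlapping in CPM, and an established symbol. For 3 against 3 libraries, chance gives groups that do not overlap for 10% of genes. The rule added up to 4 members with the smallest p from each called list and from 6 lists of fat metabolism and stem cells. For the interaction it named up to 5 genes with the smallest adjusted p in each direction, and for the averaged contrast the 5 largest changes each way without the overlap condition. Lists are quoted in order of p. The values of 1 named gene are not reported here.

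The other settings were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter, a filter of 50 counts in 3 libraries, only the groups compared, the replicate number as a block, each library left out in turn (12 fits), camera with an estimated correlation, and fry. Further settings were chosen after seeing the data. They left out both chow libraries that lie between the others of their group, or added a smooth muscle score or a proximal intestine score as a covariate. A score was the mean centred log2 of CPM plus 0.5 over the list. Tables were handled in Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

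The tests were tested on simulated data drawn from the real means, with 200 genes changed. For IEKO against floxed on chow (17363 genes) 55.2%, 89.6% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were called. For the same contrast on HFD (17358 genes) the shares were 61.2%, 92.5% and 97.0%. For HFD against chow they were 64.2%, 94.0% and 97.0% in floxed (17371 genes) and 52.2%, 97.0% and 100% in IEKO (17332 genes). For the interaction (17368 genes) they were 22.4%, 67.2% and 100%. False calls numbered 8 to 13 per simulation. The list of PPARA targets, its 37 measured members lowered 1.3-fold, was called in all 5 simulations, and 2 to 5 other lists were called beside it, while 5 of the other lists share members with it. Genes were drawn independently, and each gene had the same spread in all groups. These shares therefore do not show how the tests behave with correlated genes or with groups of unlike spread, as in the real data.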

Results

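Gene expression in mouse intestine was measured by bulk RNA-seq in a 2 by 2 design of genotype and diet. Floxed mice (Pparafl/fl) carry Ppara alleles flanked by recombinase sites and served as the control genotype. The other genotype, PparaΔIE, is called IEKO here, and its name is the usual notation for loss of Ppara in the intestinal epithelium. Ppara encodes PPARA, a nuclear receptor that binds fatty acids and drives genes of fatty acid oxidation. Male C57BL/6 mice of both genotypes received chow or a high-fat diet, given in the labels as 60% HFD, over 10 days, and each of the 4 groups held 3 libraries. Library totals averaged 44502176 ± 9623712 expected counts in floxed chow, 36787378 ± 3070444 in IEKO chow, 38365815 ± 1942753 in floxed HFD and 34315487 ± 1028620 in IEKO HFD (SD, n = 3 each). The labels do not say that the libraries of a group came from separate mice, so the p-values measure the spread between these samples, which may be technical.

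The libraries of floxed chow resembled one another more than those of the other groups. Immunoglobulin V genes carry the B cell clones of an individual animal, and across 146 of them the correlation between libraries was 0.900 to 0.958 within floxed chow, 0.721 to 0.783 within the HFD groups and 0.518 to 0.829 over 54 pairs of libraries from different groups. In IEKO chow, library 3 correlated at 0.893 with library 1 and at 0.885 with library 2, while libraries 1 and 2 correlated at 0.691. These correlations are across genes, which are not independent replicates. Of 164 genes that differed between IEKO chow 1 and 2, 99.4% lay between those libraries in IEKO chow 3. In floxed chow 1 this was 83.3% of only 12 genes that differed between libraries 2 and 3, and in the HFD libraries it was 37.9% to 77.6% of 29 to 69 genes. The biological coefficient of variation was 0.0583 in floxed chow, 0.152 in IEKO chow, 0.146 in floxed HFD and 0.140 in IEKO HFD. Counts of changed genes are therefore also given without floxed chow 1 and IEKO chow 3, a setting chosen after seeing the data. Floxed chow 2 and 3, which stay in, still correlated at 0.900 across the immunoglobulin V genes, so that setting may leave libraries that are not independent. The SDs of the chow groups are limited by the likeness of their libraries as well.

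**Figure D1:**
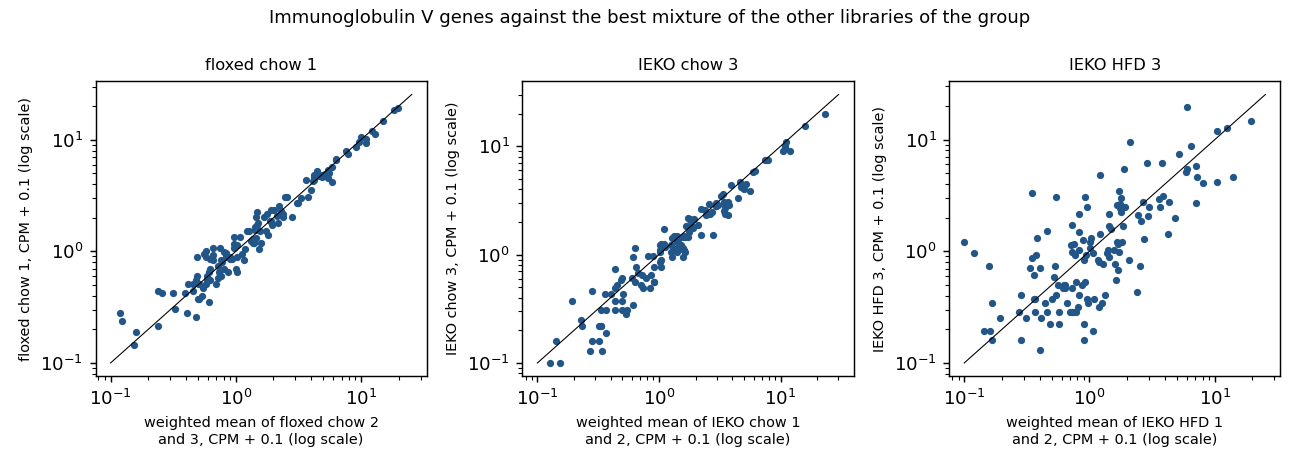
Level of each immunoglobulin V gene in floxed chow 1, IEKO chow 3 and IEKO HFD 3 (y axis, CPM + 0.1, log scale) against the weighted mean of the other libraries of its group that fitted best (x axis, CPM + 0.1, log scale). Each point is a gene and the line marks equality. The departure from the line was 1.90 and 1.91 times counting noise in the chow libraries and 7.79 times in IEKO HFD 3.

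Ppara (chromosome 15, 85734983 to 85802819, mm10) was measured in every library first, as the targeted gene. Its level was 19.2, 18.1 and 22.0 CPM in the floxed chow libraries and 8.42, 15.6 and 13 CPM in the IEKO chow libraries. On HFD it was 39.3, 36.6 and 33.7 CPM in floxed and 11.4, 11.1 and 17.3 CPM in IEKO. Every IEKO library lay below every floxed library on the same diet. The log2 fold change was -1.46 on HFD (SE 0.21, adjusted p = 0.031) and -1.07 averaged over diets (SE 0.15, adjusted p = 0.013). On chow it was -0.68 (SE 0.21) and did not pass the test (adjusted p = 0.25). Gene-level counts include reads from exons that a deletion leaves in place and from cells outside the epithelium.

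**Figure D2:**
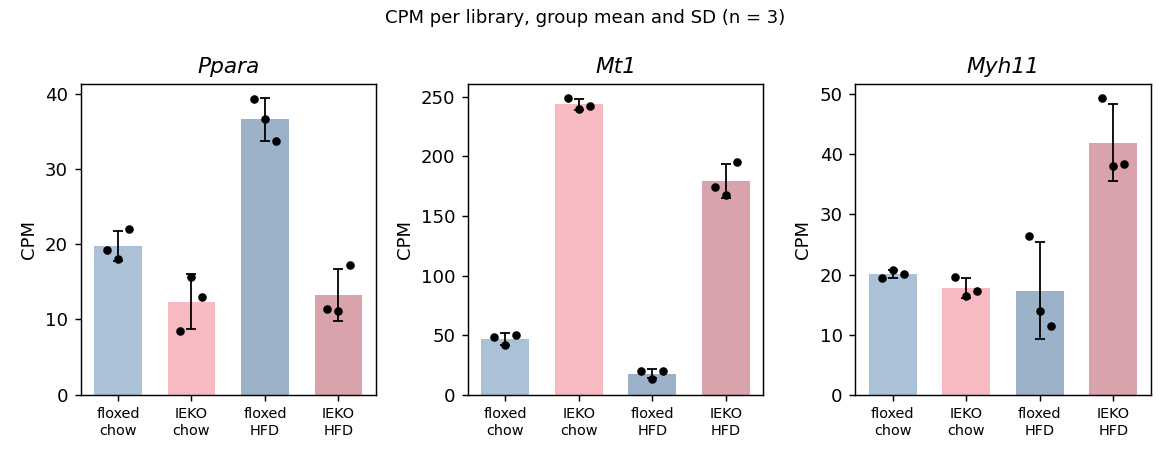
CPM of Ppara, of the metallothionein gene Mt1 and of the smooth muscle myosin gene Myh11 in each group (bars, mean; error bars, SD; points, the 3 libraries). Ppara averaged 36.6 CPM in floxed HFD and 13.3 CPM in IEKO HFD, Mt1 was above 167 CPM in every IEKO library, and Myh11 averaged 41.9 CPM in IEKO HFD and 17.3 CPM in floxed HFD.

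The comparison of IEKO with floxed mice on chow asks what the genotype changes without a high-fat load. Mt1, which encodes a metal-binding metallothionein (chromosome 8, 94179082 to 94180327), rose from 46.8 ± 4.63 to 244 ± 4.53 CPM (SD, n = 3), a 5.20-fold difference (log2 fold change 2.38, SE 0.13, adjusted p = 6.5e-07). Gip, the incretin hormone of enteroendocrine cells, rose by a log2 fold change of 1.58 (SE 0.26, adjusted p = 0.038), and Ces2a, a carboxylesterase, by 0.91 (SE 0.12, adjusted p = 0.0085). Arnt2 (1.43), Slc13a2os (1.41), Wwc2 (0.99), the tuft cell channel gene Trpm5 (0.83) and the osmotic stress factor Nfat5 (0.59) also rose. Slc13a2os is antisense to the citrate transporter gene Slc13a2, and with the strand setting unknown its reads cannot be told from those of Slc13a2. Klf6, a zinc finger transcription factor, fell from 272 ± 17 to 153 ± 18.5 CPM (log2 fold change -0.83, SE 0.12, adjusted p = 0.022). Mvk, mevalonate kinase of the cholesterol pathway, and H2-DMa, which helps load peptides on MHC class II, both fell by 0.59 on the log2 scale (adjusted p = 0.027 and 0.05).

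Among gene lists on chow, cholesterol biosynthesis was lower as a group, with 1 of 24 members (Mvk) fallen and 23 not passing, and 17 lower when adjusted over the list alone (median log2 fold change -0.34, adjusted p = 0.48 with an estimated correlation). Of 8 MHC class II genes, 1 fell (H2-DMa) and 7 did not pass, with 7 lower adjusted over the list alone (median -0.50, adjusted p = 0.48 with an estimated correlation). Xenobiotic genes regulated by PXR and CAR were higher, with 1 of 13 risen (Ces2a) and 4 higher adjusted over the list alone (median 0.47, adjusted p = 0.64 with an estimated correlation). In that list Cyp3a11 measured 3.40 ± 0.114 CPM in floxed and 22.1 ± 13.4 CPM in IEKO (adjusted p = 0.076). Tuft cell markers were higher, with 1 of 10 risen (Trpm5) and 4 higher adjusted over the list alone (median 0.32, adjusted p = 0.56 with an estimated correlation). None of 13 T cell markers passed, and 3 were lower adjusted over the list alone (median -0.50, adjusted p = 0.56 with an estimated correlation). Of 21 genes of mitochondrial fatty acid oxidation 0 passed, and 6 were lower adjusted over the list alone (median -0.26, adjusted p = 0.64 with an estimated correlation). Of 37 measured PPARA targets 0 passed over all genes and 0 when adjusted over the list alone (median -0.13, adjusted p = 0.85 with an estimated correlation). The other lower lists were blood (median -0.82), B and plasma cells (-0.33), Paneth cells (-0.29), proliferation (-0.26), myeloid cells (-0.22), glycolysis (-0.16), oxidative phosphorylation (-0.16), interferon and MHC class I (-0.15), lipogenesis (-0.15) and peroxisomal oxidation (-0.09). None of these calls held with an estimated correlation (adjusted p from 0.48 to 0.87).

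Region markers differed between the chow libraries. Lct, the lactase gene of the proximal small intestine, measured 2.33 ± 0.382 CPM in floxed chow but 0.453, 102 and 57.6 CPM in IEKO chow 1, 2 and 3. Fgf15, a bile acid response gene of the ileum, measured 14.9 ± 2.49 CPM in floxed chow and 15.1, 109 and 69.4 CPM in the same IEKO libraries. The proximal list as a whole was not called (4 genes, median 0.54), nor was the list of the distal ileum (5 genes, median -0.02).

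In all, 22 of 17602 genes differed on chow (14 higher, 8 lower), 12 of them at least 2-fold, by edgeR's quasi-likelihood test. Of these calls, 2 of the higher and 5 of the lower were immunoglobulin V genes, which vary between animals. The count was 1 (Mt1) without both mixture-like chow libraries, 53 with only the chow groups fitted, 49 without the filter, 14 with the replicate number as a block, 10 with the proximal score and 186 by DESeq2. It was 1 without floxed chow 1 or IEKO chow 3, 6 without IEKO chow 2, 7 and 8 without floxed chow 2 and 3, 13 without IEKO HFD 2, 45 without floxed HFD 1 and 517 without IEKO chow 1. Of the 11 named genes called here, 1 (Mt1) was called in every fit that left out a library, and the others in 2 to 9 of the 12 fits. No list call, of 17, held with an estimated correlation.

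On HFD the same genotype comparison addresses the role of epithelial PPARA under a fat load. Of 22 genes of peroxisomal and 21 of mitochondrial fat oxidation, 1 and 2 fell in IEKO, and neither list was called with an estimated correlation (adjusted p = 0.16 and 0.18). Acaa1b, a peroxisomal thiolase (chromosome 9, 119148023 to 119157093), fell from 12.8 ± 4.80 to 2.55 ± 1.18 CPM (log2 fold change -2.34, SE 0.36, adjusted p = 0.031). Acadvl and Acads, dehydrogenases of mitochondrial acyl-CoA, fell by 0.64 and 0.49, and the fatty aldehyde dehydrogenase gene Aldh3a2 fell by 0.57. Paqr7, a membrane progestin receptor gene (chromosome 4, 134496697 to 134510235), fell from 12.7 ± 1.88 to 4.40 ± 0.907 CPM (log2 fold change -1.53, SE 0.18, adjusted p = 0.0029).

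Mt1 was 10.2-fold higher in IEKO on HFD (log2 fold change 3.35, SE 0.14, adjusted p = 1.3e-08), at 179 ± 14.2 against 17.6 ± 3.83 CPM. S100g, the intestinal calcium-binding protein induced by vitamin D, was 2.01-fold higher (log2 fold change 1.01, SE 0.12, adjusted p = 0.0029). Synm (1.23) and Flnc (1.19), which encode muscle filament proteins, rose, as did Ppp1r12b (0.67), a subunit of myosin phosphatase. Gsdmc3 (0.89), Kifc5b (0.71) and Klf7 (0.56) rose as well. Further decreases were in the channel gene Aqp3 (-1.88), the sulfotransferase gene Gal3st2b (-1.78), the cytochrome P450 gene Cyp2c65 (-1.16) and the colipase gene Clps (-0.83). Treh, the brush border trehalase, fell by 0.58, the crypt base marker Smoc2 by 0.47 and the bilirubin glucuronosyltransferase gene Ugt1a1 by 0.72. The defensin gene Defa32, which is outside the Paneth cell list, fell by 0.87, and of that list Lyz1, Defa22 and Defa21 fell by 0.72, 0.73 and 0.73, although reads of defensin and Cyp2c genes can be shared among near copies.

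The list of PPARA targets was lower in IEKO on HFD. Of its 37 measured members 3 fell (Acaa1b, Acadvl and Aldh3a2) and 34 did not pass, and 30 were lower adjusted over the list alone (median -0.41, adjusted p = 0.16 with an estimated correlation). Mitochondrial fatty acid oxidation, which shares 15 of its 21 members with that list, had 2 fallen and 18 lower adjusted over the list alone (median -0.37, adjusted p = 0.18 with an estimated correlation). Peroxisomal oxidation had 1 of 22 fallen and 14 lower adjusted over the list alone (median -0.26, adjusted p = 0.16 with an estimated correlation). Fatty acid uptake and binding had 0 of 13 passing over all genes and 8 lower adjusted over the list alone (median -0.41, adjusted p = 0.16 with an estimated correlation). There, Got2 had a log2 fold change of -0.37 (SE 0.08, adjusted p = 0.09), the fatty acid binding protein gene Fabp1 of -2.85 (SE 0.53, adjusted p = 0.093) and Fabp2 of -0.64 (SE 0.15, adjusted p = 0.11). Omega-oxidation had 1 of 5 fallen and 2 lower adjusted over the list alone (median -0.41, adjusted p = 0.38 with an estimated correlation). Chylomicron and triglyceride genes had 0 of 26 passing and 3 lower adjusted over the list alone (median -0.22, adjusted p = 0.30 with an estimated correlation).

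Smooth muscle markers stood higher in the same IEKO HFD libraries. Of 10 members 1 rose (Synm) and 9 did not pass, and 9 were higher adjusted over the list alone (median 1.03, adjusted p = 0.16 with an estimated correlation). Myh11 measured 41.9 ± 6.38 CPM in IEKO HFD and 17.3 ± 8.05 CPM in floxed HFD (adjusted p = 0.091). Paneth cell genes were lower, with 3 of 15 fallen and 14 lower adjusted over the list alone (median -0.57, adjusted p = 0.18 with an estimated correlation). Epithelial antimicrobial genes were higher as a list with 0 of 15 passing, also over the list alone (median 0.50, adjusted p = 0.57 with an estimated correlation). Mature enterocyte markers had 1 of 14 fallen (Treh), 1 also over the list alone (median -0.10, adjusted p = 0.57 with an estimated correlation), and the sign of that median turned with the muscle score as a covariate (0.02). Stem cell markers had 1 of 15 fallen (Smoc2), 1 also over the list alone (median -0.16, adjusted p = 0.57 with an estimated correlation). Medians of the other lower lists were -0.49 for pancreatic acinar genes (4 measured), -0.26 for endothelium, -0.22 for T cells, -0.22 for retinoid metabolism, -0.21 for myeloid cells, -0.17 for lipogenesis, -0.16 for carbohydrate digestion, -0.16 for oxidative phosphorylation, -0.15 for sterol transport, -0.14 for NRF2 targets, -0.12 for xenobiotic genes and -0.10 for cholesterol biosynthesis. These calls were lost with an estimated correlation (adjusted p from 0.18 to 0.62). The long noncoding RNA gene Gm26917, singled out after its values were seen, took 33590 ± 2438 CPM in IEKO HFD and 18815 ± 2275 CPM in floxed HFD (log2 fold change 0.84, SE 0.14, adjusted p = 0.031). In the same libraries protein-coding genes took 78.7% ± 1.23 of counts in IEKO HFD and 81.2% ± 0.689 in floxed HFD, with no overlap between libraries. Nuclear-encoded rRNA genes took 0.331% ± 0.0875 in IEKO HFD and 0.193% ± 0.0123 in floxed HFD. Whether Gm26917 differed in expression or with the RNA classes that the libraries held was not tested.

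**Figure D3:**
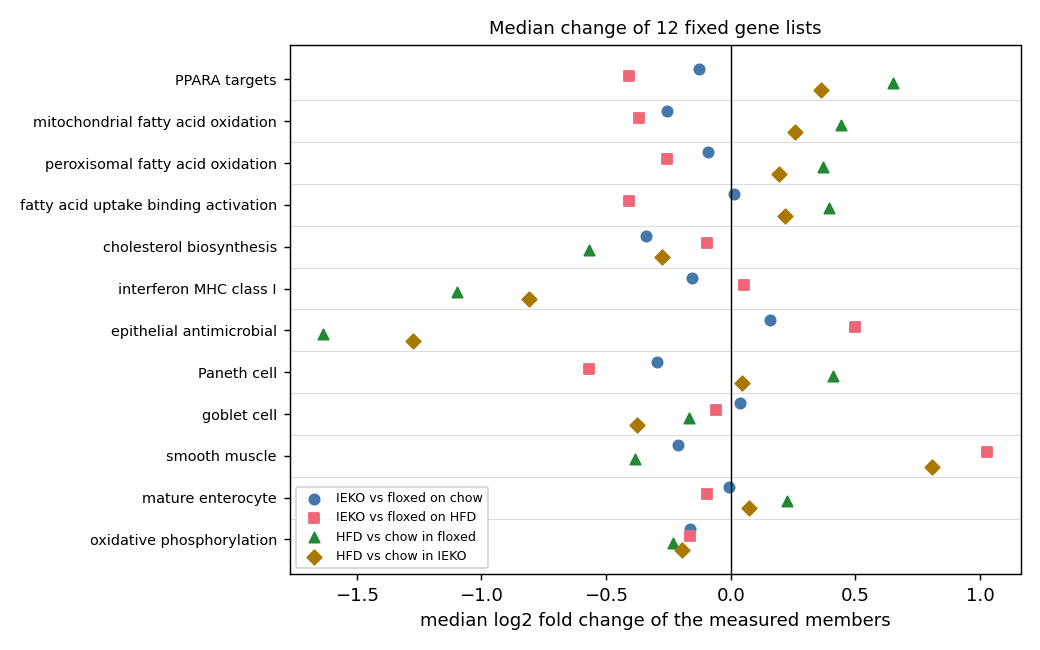
Median log2 fold change of the measured members of 12 gene lists (x axis) in the 4 pairwise comparisons (symbols). PPARA targets lie at -0.41 in IEKO against floxed mice on HFD and at 0.65 in the HFD response of floxed mice, and smooth muscle markers lie at 1.03 in IEKO against floxed mice on HFD.

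By edgeR, 51 genes differed between genotypes on HFD (18 higher, 33 lower), 13 of them at least 2-fold. The count was 3 (Mt1, S100g and Paqr7) without both mixture-like chow libraries, 6 with only the HFD groups fitted, 94 without the filter, 1523 with the muscle score and 288 by DESeq2. It was 5 without floxed chow 1, 2 or 3 or IEKO HFD 2, 6 without floxed HFD 2, 7 without IEKO chow 3 or IEKO HFD 1, 27 without floxed HFD 1, 103 without floxed HFD 3 and 173 without IEKO HFD 3. Floxed chow is not part of this comparison, but the single fit shares its estimate of spread over all groups. That group had the lowest biological coefficient of variation (0.0583), and most of the 51 calls depended on its libraries. Of the 25 named genes called here, 3 (Mt1, S100g and Paqr7) were called in every fit that left out a library, and the others, PPARA targets and Ppara included, in 1 to 9 of the 12 fits. With only the HFD groups fitted, 5 of the 25 were called. Of 23 list calls 0 held with an estimated correlation. Between diets, 2 genes were higher in IEKO in both comparisons (Mt1 and Gm15675, 0.0143 by chance) and 1 was lower in both (Klf6, 0.015 by chance). These chance numbers take the calls of both diets as independent.

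The HFD response of floxed mice compares the diets with Ppara intact. The proximal score ran from -1.002 to -0.899 in floxed chow and from 0.048 to 1.052 in floxed HFD. Effects of the diet and of the stretch of intestine sampled therefore cannot be told apart in this comparison. PPARA targets rose broadly, with 29 of 37 members risen, 8 not passing and 30 higher adjusted over the list alone (median 0.65, adjusted p = 0.29 with an estimated correlation). Fabp2 rose from 2121 ± 92.4 to 5724 ± 753 CPM (log2 fold change 1.43, SE 0.15, adjusted p = 0.0002), Acaa1b rose 13.6-fold, and Angptl4 and Creb3l3, regulators of triglyceride clearance, rose by 2.22 and 1.75 on the log2 scale. Pdk4, the kinase that shuts off pyruvate oxidation, rose from 0.114 ± 0.0804 to 24.3 ± 4.60 CPM (log2 fold change 7.78, SE 1.18, adjusted p = 0.0055), from a base of a few counts per library. Fabp1 (5.48), Acot12 (5.26) and Gimd1 (4.61) were also among the largest increases, and Ppara itself rose 1.85-fold. The largest decreases included Plet1 (-5.55), the tachykinin gene Tac1 (-3.07), the metallothionein gene Mt2 (-2.69) and the neutrophil antigen gene Cd177 (-2.41), with the near copies Gml (-2.75) and Gml2 (-2.66). Immunoglobulin V genes Igkv9-124 (4.15), Ighv10-3 (4.14), Ighv3-1 (-2.56) and Ighv1-7 (-2.43) are in the same range.

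Fat handling lists rose with HFD in floxed mice. Mitochondrial oxidation had 14 of 21 risen, 1 fallen and 6 not passing, with 16 higher and 1 lower adjusted over the list alone (median 0.44, adjusted p = 0.34 with an estimated correlation), led by Cpt2 (0.65) and Slc25a20 (0.87), which bring acyl groups into mitochondria. Peroxisomal oxidation had 10 of 22 risen and 1 fallen, as adjusted over the list alone (median 0.37, adjusted p = 0.32 with an estimated correlation), led by Scp2 (0.80), Cat (1.37) and Hsd17b4 (1.66). Fatty acid uptake had 7 of 13 risen, with 9 higher and 1 lower adjusted over the list alone (median 0.39, adjusted p = 0.29 with an estimated correlation). Of 26 triglyceride and chylomicron genes 10 rose and 1 fell, as adjusted over the list alone (median 0.17, adjusted p = 0.45 with an estimated correlation), including Apob (1.01) and Apoa4, which went from 189 ± 46.1 to 1917 ± 921 CPM (log2 fold change 3.34). Retinoid genes had 5 of 12 risen and 7 adjusted over the list alone (median 0.46, adjusted p = 0.29 with an estimated correlation), led by Rbp2 (1.72) and Retsat (2.28). Sterol transport had 6 of 11 risen and 7 adjusted over the list alone (median 0.45, adjusted p = 0.29 with an estimated correlation), led by the cholesterol exporter gene Abca1 (1.64).

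Cholesterol synthesis and defence genes fell with HFD in floxed mice. Of 24 cholesterol genes 17 fell and 18 adjusted over the list alone (median -0.57, adjusted p = 0.29 with an estimated correlation), with Mvk at -0.66 and Mvd at -0.75. Of 26 interferon and MHC class I genes 20 fell and 24 adjusted over the list alone (median -1.10, adjusted p = 0.29 with an estimated correlation), including Ifit2 (-2.05), Oas1a (-1.0) and Tap1 (-1.67). Epithelial antimicrobial genes had 13 of 15 fallen, and 14 lower and 1 higher adjusted over the list alone (median -1.64, adjusted p = 0.29 with an estimated correlation). Among them Lypd8 fell by 1.08, and Reg3b went from 25450 to 6196 CPM (log2 fold change -2.04), a value that can share reads with Reg3g (-2.10). Glycolysis had 7 of 14 fallen and 11 adjusted over the list alone (median -0.27, adjusted p = 0.33 with an estimated correlation), led by the glucose transporter gene Slc2a1 (-0.62). Medians of the other higher lists were 0.69 for xenobiotic genes, 0.65 for omega-oxidation, 0.59 for endothelium, 0.41 for Paneth cells, 0.38 for carbohydrate digestion, 0.34 for tuft cells and 0.23 for mature enterocytes (adjusted p from 0.29 to 0.50 with an estimated correlation). The other lower lists had medians of -0.89 (blood), -0.39 (proliferation), -0.38 (smooth muscle), -0.32 (MHC class II), -0.25 (T cells), -0.23 (oxidative phosphorylation) and -0.17 (goblet cells), with adjusted p from 0.34 to 0.50 with an estimated correlation.

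Some markers of both ends of the small intestine differed in this comparison. Lct rose from 2.33 ± 0.382 to 164 ± 90.1 CPM (log2 fold change 6.15, SE 1.44, adjusted p = 0.028). The ileal genes Fgf15 and Cubn, set beside it after their values were seen, rose by 2.79 (SE 0.63, adjusted p = 0.024) and 1.11 (SE 0.25, adjusted p = 0.017) on the log2 scale. Gata4, another gene of the proximal list, did not pass (log2 fold change 1.24, SE 0.80, adjusted p = 0.35). The brush border gene Vil1 had a log2 fold change of -0.08 (SE 0.11). The proximal list had a median of 0.83 and the distal list one of 0.11, and neither was called.

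In floxed mice 2353 genes differed between HFD and chow by edgeR (1197 higher, 1156 lower), 500 of them at least 2-fold. The count was 458 without both mixture-like chow libraries, of which 453 were among the 2353, and it was 71 with the proximal score and 975 with the muscle score. Of the 101 named genes called here, 51 were called without the mixture-like libraries and 16 with the proximal score. The count was 896, 1150 and 895 without floxed chow 1, 2 and 3, and 1300 and 1198 without floxed HFD 2 and 3. Of 25 list calls 0 held with an estimated correlation, while fry called 18 lists (12 higher, 6 lower).

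In IEKO mice PPARA targets also stood higher on HFD than on chow. Of 37 members 12 rose and 25 did not pass, with 22 higher and 1 lower adjusted over the list alone (median 0.36, adjusted p = 0.69 with an estimated correlation), led by Pex11a (0.61), Slc25a20 (0.81), Cpt2 (0.55) and Angptl4 (1.26). Pdk4 rose by 5.52 (SE 1.15, adjusted p = 0.025), the glucose-6-phosphatase gene G6pc by 2.71 and Apoa4 by 1.93. The call of Pdk4 was lost with only the IEKO groups fitted and with the muscle or the proximal score. The heat shock genes Hspa1a and Hspa1b, near copies that can share reads, rose by 2.97 and 2.49. Zbtb16 (1.95), the cation channel gene Trpc1 (1.76) and Grem1 (1.72), a BMP antagonist of stromal cells, rose too. Plet1 (-5.40), Tac1 (-2.88), Mt2 (-2.82), Cd177 (-2.63), Cyp3a11 (-2.50), Gbp2 (-2.39), Gml2 (-2.28) and Igkv4-72 (-3.16) were the largest decreases. Fabp2 rose by 0.78 (SE 0.15, adjusted p = 0.0081). For the PPARA target median, the farthest other division of these libraries into 3 against 3 gave 0.29. The proximal score ran from -1.366 to 0.589 in IEKO chow and from -0.231 to 0.925 in IEKO HFD. Effects of the stretch of intestine sampled are therefore not excluded in this comparison either.

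Interferon, antimicrobial and goblet cell lists were lower on HFD in IEKO mice. Interferon and MHC class I genes had 14 of 26 fallen and 20 adjusted over the list alone (median -0.81, adjusted p = 0.57 with an estimated correlation). Antimicrobial genes had 10 of 15 fallen and 13 adjusted over the list alone (median -1.28, adjusted p = 0.57 with an estimated correlation), with Lypd8 at -0.87 and Reg3b at -1.46. Goblet cell genes had 4 of 9 fallen and 7 adjusted over the list alone (median -0.38, adjusted p = 0.26 with an estimated correlation), namely Spink4 (-1.43), Spdef (-0.50), Tff3 (-0.49) and Agr2 (-0.39). Cholesterol biosynthesis had 6 of 24 fallen and 10 adjusted over the list alone (median -0.28, adjusted p = 0.69 with an estimated correlation). NRF2 and glutathione genes had 4 of 16 fallen, with 5 lower and 2 higher adjusted over the list alone (median -0.18, adjusted p = 0.69 with an estimated correlation), led by Gsta3 (-1.67). Mitochondrial oxidation had 5 of 21 risen and 1 fallen, with 10 higher and 2 lower adjusted over the list alone (median 0.26, adjusted p = 0.76 with an estimated correlation). Smooth muscle markers had 3 of 10 risen (Synm, Mylk and Myh11) and 7 adjusted over the list alone (median 0.81, adjusted p = 0.57 with an estimated correlation). The remaining called lists had medians of 0.46 (retinoid metabolism), 0.23 (sterol transport), 0.13 (unfolded protein response), -0.20 (glycolysis), -0.20 (oxidative phosphorylation) and -0.15 (proliferation), with adjusted p from 0.57 to 0.80 with an estimated correlation.

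In IEKO mice 1444 genes differed between HFD and chow by edgeR (606 higher, 838 lower), 256 of them at least 2-fold. The count was 185 without both mixture-like chow libraries, of which 179 were among the 1444, and 309 with only the IEKO groups, 718 with the proximal score and 2594 with the muscle score. Of the 68 named genes called here, 18 were called without the mixture-like libraries, and Pdk4, G6pc, Apoa4, Pex11a, Slc25a20, Cpt2 and Angptl4 were not among them. The count was 704, 2551 and 451 without IEKO chow 1, 2 and 3, and 856 and 738 without IEKO HFD 1 and 2. Of 14 list calls 0 held with an estimated correlation, and other divisions of these libraries into 3 against 3 gave a median of 14 list calls.

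The diet responses of both genotypes, which share no libraries, overlapped. Higher in both were 313 genes (41.2 by chance) and lower in both 532 (55.0 by chance). The chance numbers take the calls as independent, although a single fit shares its estimate of spread between both comparisons. Only 2 genes went opposite ways, Ighv1-22 and, named after its values were seen, the desmocollin gene Dsc3. The correlation of log2 fold changes across genes was 0.44 over all tested genes and 0.83 over 4465 genes with a mean log2 CPM of at least 5. Genes are not independent replicates. A difference in the stretch of intestine sampled that both genotypes share would also give overlap and correlation. With the proximal score the counts of changed genes were 71 in floxed and 718 in IEKO. The overlap was not computed with that score or without the mixture-like libraries.

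**Figure D4:**
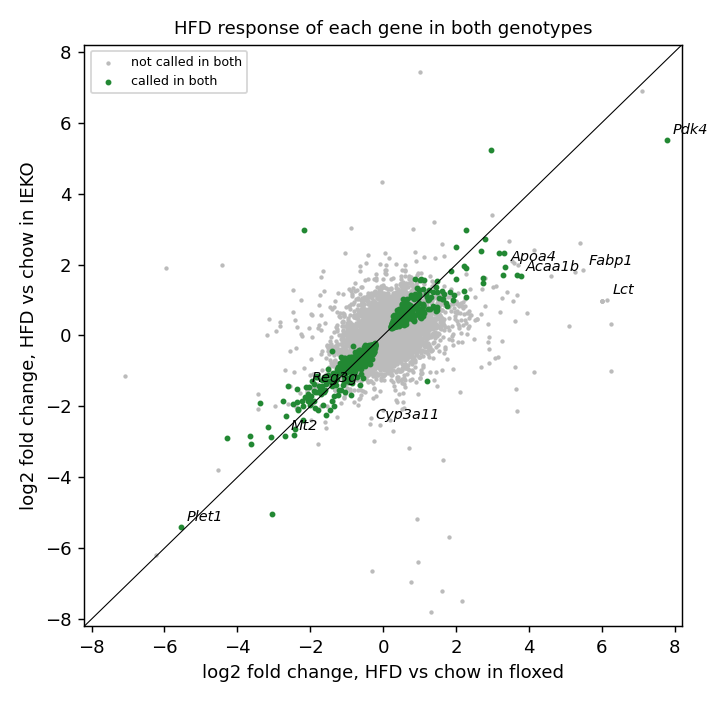
Log2 fold change of HFD against chow in floxed mice (x axis) and in IEKO mice (y axis). Each point is a tested gene, green points were called in both genotypes, the diagonal marks equal responses, and 1 gene lies outside the axes. Pdk4 (7.78 and 5.52) and Plet1 (-5.55 and -5.40) mark the ends of the shared response, and Fabp1 lies at 5.48 in floxed mice and 1.84 in IEKO mice.

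The interaction asks whether the diet response depended on genotype, and a single gene passed. Ighv1-22, an immunoglobulin V gene with near copies, measured 0.775, 2.84, 1.82 and 1.15 CPM in floxed chow, IEKO chow, floxed HFD and IEKO HFD (log2 interaction -2.49, SE 0.34, adjusted p = 0.046). Ppara had an interaction of -0.78 (SE 0.30, adjusted p = 0.74) and Mt1 of 0.97 (SE 0.18, adjusted p = 0.33). PPARA targets had 0 of 37 members passing over all genes and 8 lower adjusted over the list alone (median -0.24, adjusted p = 0.37 with an estimated correlation). Smooth muscle markers had 0 of 10 passing and 7 higher adjusted over the list alone (median 1.39, adjusted p = 0.19 with an estimated correlation). At an unadjusted p under 0.05 edgeR counted 1116 of 17602 genes, where 5% would lie with no change, and DESeq2 called 57. The count of 1 became 0 without both mixture-like chow libraries, with the stricter filter, with the replicate number as a block, with the proximal score, or without floxed chow 1, floxed chow 2, IEKO chow 2, IEKO chow 3 or floxed HFD 2. Without IEKO HFD 1 or 2 it was 1, but Ighv1-22 no longer passed, and of the 12 fits that left out a library 5 called Ighv1-22. The count was 4 without the filter or without IEKO HFD 3, 7 without floxed HFD 3, 19 without IEKO chow 1 or floxed HFD 1, and 61 with the muscle score.

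Averaged over diets, IEKO differed from floxed mice most in Mt1, which was 7.28-fold higher (log2 fold change 2.86, SE 0.10, adjusted p = 6.4e-10). Klf6 fell by 0.81 (SE 0.09, adjusted p = 0.0016) and Paqr7 by 1.15 (SE 0.13, adjusted p = 0.0019), and these 3 genes were called in every fit that left out a library. Cyp3a11 (1.62), the midline gene Mid1 (1.04), Gip (0.81) and Slc13a2os (0.78) rose, and Aqp3 (-1.09) and Ighv1-7 (-2.41) fell. Of the 12 fits that left out a library, Cyp3a11 was called in 1, Gip and Aqp3 in 3, and Mid1, Slc13a2os and Ighv1-7 in 5. PPARA targets had 5 of 37 fallen and 24 lower adjusted over the list alone (median -0.29, adjusted p = 0.36 with an estimated correlation). Paneth cell genes had 8 of 15 fallen and 14 adjusted over the list alone (median -0.42, adjusted p = 0.34 with an estimated correlation). Mitochondrial oxidation had 5 of 21 fallen and 18 adjusted over the list alone (median -0.30, adjusted p = 0.34 with an estimated correlation). Fatty acid uptake had 2 of 13 fallen and 6 adjusted over the list alone (median -0.31, adjusted p = 0.34 with an estimated correlation). T cell markers had 1 of 13 fallen and 7 adjusted over the list alone (median -0.38, adjusted p = 0.48 with an estimated correlation), beside smooth muscle markers with 0 of 10 risen and 3 adjusted over the list alone (median 0.32, adjusted p = 0.48 with an estimated correlation).

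The averaged contrast called 262 genes by edgeR (113 higher, 149 lower), 18 of them at least 2-fold. It called 3 genes (Mt1, Paqr7 and Klf6) without both mixture-like chow libraries, 978 by DESeq2 and 2739 with the muscle score. The count was 11, 59 and 40 without floxed chow 1, 2 and 3, and 1463, 61 and 11 without IEKO chow 1, 2 and 3. It was 139, 113 and 417 without floxed HFD 1, 2 and 3, and 114 and 91 without IEKO HFD 1 and 2. Of 17 list calls 0 held with an estimated correlation.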

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

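The tests with the smooth muscle or proximal score, the permutation test over genes and the counts of other groupings for genes and lists were chosen only after the results were seen, and the 100 groupings for the PPARA target median were set before. Each result of this part was picked out because the genotype difference, or its list median, differed between diets by the interaction test. For genes, Ighv1-22 had a log2 interaction of -2.49 (edgeR, adjusted p = 0.046). Of 100 groupings that shuffled genotype within each diet, the real one included, 7 gave as many interaction genes, so chance is not excluded for this count of 1. The highest other grouping gave 262, and it swaps genotype on a single diet, which turns the interaction into the averaged genotype contrast.

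For lists, camera with the preset correlation called 26 interactions, and 3 of the 100 groupings, the real one included, gave as many (highest other 26). Shuffling genotype within each diet also breaks up the genotype difference, so the groupings do not stand for the absence of an interaction alone. They also presume that the libraries are independent samples. Chance is therefore not excluded for the number of lists or for any single one. With an estimated correlation camera called 0 of the 26 (adjusted p from 0.19 to 0.65, and 5 lists at an unadjusted p under 0.05), and fry called 0 (6 at an unadjusted p under 0.05). Medians below 0, a lower HFD response in IEKO than in floxed mice, were -0.71 for xenobiotic genes of PXR and CAR, -0.55 for adipocyte markers, -0.47 for fatty acid uptake, -0.44 for omega-oxidation and -0.37 for tuft cells. They were -0.29 for Paneth cells, -0.24 for PPARA targets, -0.22 for endothelium, -0.21 for retinoid metabolism, -0.21 for goblet cells, -0.20 for mature enterocytes and -0.19 for peroxisomal oxidation. They were -0.17 for sterol transport, -0.16 for triglyceride and chylomicron genes, -0.14 for mitochondrial oxidation, -0.14 for carbohydrate digestion and -0.11 for NRF2 targets. Medians above 0 were 1.39 for smooth muscle, 0.66 for blood, 0.58 for MHC class II, 0.27 for epithelial antimicrobial genes, 0.24 for cholesterol biosynthesis, 0.23 for interferon and MHC class I, 0.23 for T cells, 0.14 for proliferation and 0.10 for the unfolded protein response. For the PPARA target median, 31 of 100 groupings lay as far from 0 (farthest other 0.58, from the grouping that swaps genotype on a single diet). Groupings near that swap also carry the genotype difference into the interaction. The share of 31 therefore cannot decide the question, and chance is not excluded.

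The lower level of PPARA targets in IEKO mice on HFD (median -0.41, farthest other of the 10 splits -0.34, too few splits for a share under 0.05) was weighed against the higher smooth muscle markers of the same libraries. More muscle tissue would lower all epithelial genes alike, but PPARA targets had a median of -0.41 (37 genes) and mature enterocyte markers of -0.10 (14 genes), a difference with p = 4e-04 (two-sided permutation test over genes, 100000 resamples, genes not being independent). With the muscle score as a covariate the PPARA target median was -0.53. A different stretch of intestine was set against the same pattern, and with the proximal score as a covariate the median stayed at -0.40 (-0.4035), below the bound of -0.2 set for it, though that score rests on 4 genes. The proximal scores overlapped between genotypes on HFD (0.048 to 1.052 in floxed, -0.231 to 0.925 in IEKO). The adjustment could therefore move the median little, and it cannot decide about a difference in region that these 4 genes miss. The lists fell unequally, which even dilution by muscle would not give, but the permutation p does not measure the spread between libraries. Neither explanation is therefore excluded. Reduced PPARA activity is a candidate explanation that no test here separates from other effects of the genotype.

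The muscle markers themselves are 10 measured genes, of which 9 reach 1 CPM in floxed chow and 0 belong to another list, and the most abundant was Mylk at 161 ± 4.51 CPM in floxed HFD and 172 ± 24.6 CPM in IEKO HFD.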

How the results depend on the processing

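Tests without both mixture-like chow libraries and tests with the muscle or proximal score were chosen only after the results were seen. The cause of a change was not tested. Fewer libraries leave fewer degrees of freedom, but this cannot account for counts that rose, such as from 22 to 53 with only the chow groups fitted. DESeq2 size factors in edgeR moved no count over 1.5 times (28, 52, 2314, 1432, 1 and 265 genes in the order of the report). Order here is IEKO against floxed on chow and on HFD, HFD against chow in floxed and in IEKO, interaction, and average. Without the filter, counts were 49 on chow, 94 on HFD and 4 for the interaction, and the stricter filter gave 0 for the interaction. DESeq2 called 186, 288, 57 (interaction) and 978 (average). Fitting only the groups compared gave 53, 6 and, in IEKO, 309. Without both mixture-like libraries the counts were 1, 3, 458, 185, 0 and 3. With the muscle score they were 1523 (HFD), 975, 2594, 61 and 2739, and with the proximal score 10 (chow), 71, 718 and 0 (interaction). Counts of 0 for the interaction compare with 1116 of 17602 genes at an unadjusted p under 0.05, where 5% would lie with no change.

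List counts were 0 in all 6 contrasts by camera with an estimated correlation (3, 7, 7, 3, 5 and 6 at an unadjusted p under 0.05). With fry they were 0 (chow), 7 (HFD), 18 (HFD in floxed), 6 (HFD in IEKO), 0 (interaction) and 4 (average), with 7 and 6 lists at an unadjusted p under 0.05 where the count was 0. With the muscle score 14 lists were called on HFD and 16 for the interaction. The median of the interferon list on chow turned to 0.0026 without IEKO chow 2 (range without 1 library -0.3584 to 0.0026) and to 0.0176 with the proximal score. With the muscle score, mature enterocytes on HFD went to 0.0153, and the interaction to -0.7112 (blood), 0.12 (mature enterocytes), -0.5719 (proliferation) and -0.019 (unfolded protein response). The camera direction of the interaction, not the median, turned for carbohydrate digestion with the muscle score (-0.1126) and for antimicrobial genes with the proximal score (0.1082). The correlation of both diet responses was 0.8268 over genes with a mean log2 CPM of at least 5.

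Leaving out each library in turn gave 1 to 517 genes on chow, 5 to 173 on HFD, 895 to 3089 and 451 to 2551 for HFD in floxed and IEKO, 0 to 19 for the interaction and 11 to 1463 for the average. Lists ran from 15 to 18, 16 to 25, 23 to 26, 11 to 19, 21 to 27 and 17 to 24, and the correlation from 0.3308 to 0.4536. Over these fits, results of named genes were the same 4078 times, weaker 547 times and stronger 79 times. The same includes genes called in neither fit. Of named genes called with all libraries, 1 of 11, 3 of 25, 62 of 101, 37 of 68, 0 of 1 and 3 of 10 were called in all 12 of these fits. For named lists this was 1370 times the same, 93 times weaker and 1 time reversed (the interferon list). No named gene reversed under any setting run. Without both mixture-like libraries 252 results of named genes were the same and 140 weaker, and with DESeq2 342 were the same, 49 stronger and 1 weaker.

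Replicate numbers were not taken to pair the libraries, since not every same-numbered residual correlation was over 0.1. All 3 were only between IEKO chow and floxed HFD (0.152, 0.189 and 0.123), 1 of the 6 pairs of groups, which stand on opposite sides of the averaged contrast. Residual correlations of same-numbered libraries ran from -0.193 to 0.266 (7 of 18 over 0.1), those of other pairs from -0.372 to 0.429 (8 of 36), and 6 of 12 libraries correlated best with their own number. With the replicate number as a block the counts were 14, 41, 2439, 1463, 0 and 378. Of these, 12, 34, 2164, 1287, 0 and 246 were also called without the block.

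Depth of 33620991 counts or more left genes under 1 CPM, such as Pdk4 on chow, with few counts and wide errors.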

Other observations

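All tests in this part except the groupings for the PPARA target median were chosen only after the results were seen.

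Of 113 genes higher in IEKO averaged over diets 41 were neither protein-coding nor immunoglobulin or T cell receptor genes (36.3%, against 18.0% of all tested genes), and of 149 lower genes 4 were (2.7%). These shares were not tested, and they rest on a count of 262 that was 3 without both mixture-like chow libraries. Gm26917 averaged 22773, 27694, 18815 and 33590 CPM in floxed chow, IEKO chow, floxed HFD and IEKO HFD (averaged log2 fold change 0.56, SE 0.10, adjusted p = 0.019). Malat1, an abundant nuclear RNA, measured 2086, 3132, 2815 and 3664 CPM in the same order (0.48, SE 0.08, adjusted p = 0.014). Both were picked after their values were seen, and neither was among those 3 genes. Exon length had medians of 5007 bases in the higher and 2391 bases in the lower genes, against 3767.5 bases in all tested genes. Such a split was not particular to the genotype contrast. For HFD against chow the medians were 5553 and 3269 bases in floxed and 6556 and 2965 bases in IEKO. Over all genes with a length, the averaged log2 fold change correlated with log2 exon length at only 0.053. Protein-coding genes took 77.2% to 79.4% of counts in the IEKO HFD libraries and 80.5% to 81.9% in floxed HFD, and 79.8% to 81.2% in IEKO chow and 80.4% to 83.1% in floxed chow. Nuclear-encoded rRNA genes took 0.331% ± 0.0875 in IEKO HFD and 0.193% ± 0.0123 in floxed HFD, and 0.296% ± 0.0177 in IEKO chow and 0.223% ± 0.0584 in floxed chow (SD, n = 3), without overlap of genotypes on either diet, which chance gives for 10% of quantities per diet. The annotation class that holds the noncoding RNAs 7SL and 7SK took 9.53% to 11.8%.

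In each chow group 1 library lies between the others: IEKO chow 3 was fitted by a mixture with weight 0.456 of library 1 (95% bootstrap interval 0.425 to 0.470), and floxed chow 1 with weight 0.339 of library 2 (0.245 to 0.411). Against libraries of separate animals stands the departure of immunoglobulin V genes from such a mixture, at most 1.91 times counting noise in these libraries and at least 7.79 times in the HFD libraries, although the other chow libraries also lay below that, at 2.78 and 2.63 (floxed chow 2 and 3) and 5.31 and 2.2 (IEKO chow 1 and 2), with fitted weights outside 0 to 1. Against a library deposited more than once stands the lowest departure between chow libraries of a group, 1.97 times counting noise. A candidate explanation is RNA or tissue shared between libraries of a group, since the weight fitted on immunoglobulin V genes alone was 0.521 in IEKO chow 3 (0.248 to 0.551) and 0.478 in floxed chow 1 (0.291 to 0.797), with intervals that overlap those of the other genes. At which step material would have been shared stays open.

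Mt1 was higher in all 6 IEKO libraries than in any floxed library. A metal response of the tissue would raise Mt2 along with Mt1, but the 95% interval of the averaged log2 fold change of Mt2 ended at 0.799, below the start of that of Mt1 at 2.68. A candidate explanation is a transcript that carries Mt1 sequence and comes with the genotype, such as a recombinase transgene with a metallothionein 3' end. The Mt1 of IEKO beyond the floxed level was 0.821 ± 0.046 (SE) of its chow value on HFD, while Mt1 of floxed mice was 0.376 ± 0.052 of its own. Loss of PPARA in the epithelium cannot be told apart from it, since 0 libraries of a genotype with recombinase and no deletion were analysed here, and gene-level counts do not show where in Mt1 the reads lie.

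For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In genes changed, 1 split, the real one, reached the real count in each of the 4 pairwise comparisons, with 22 genes on chow (highest other 0), 51 on HFD (2), 2353 for HFD in floxed (1) and 1444 for HFD in IEKO (2). In list calls the real value was 17 on chow (highest other 14), 23 on HFD (27, with 3 splits as high), 25 for HFD in floxed (18) and 14 for HFD in IEKO (20, with 7 splits as high). The median of the other splits was 8 list calls on chow and 14 in each of the other pairwise comparisons. For the averaged contrast 1 of 100 groupings, the real one, gave 262 genes (highest other 5), which excludes chance for that count only if the 12 libraries are independent samples. Without both mixture-like libraries, which may share RNA with their group, the count was 3. List calls of that contrast did not stand out, with 34 of 100 groupings reaching 17 (highest other 26). The PPARA target median of the averaged contrast, -0.29, was reached by 1 of 100 groupings, the real one (farthest other -0.24), with the same condition.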
